A study of Drosophila melanogaster with 6 samples.

How the data were processed

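RNA of Drosophila larvae was measured on 6 single-colour Affymetrix arrays, 3 of wild type larvae, whose strain the labels write as cancon S, and 3 of larvae homozygous for a mutation of maleless (mle/mle). The genotype labels name a strain for the wild type larvae only, so the design does not set a strain difference apart from mle. The labels call the mle/mle larvae male and do not give the sex of the wild type larvae. They call the arrays biological replicates without saying how many larvae each holds. P-values therefore measure the spread between these RNA samples.

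The main values were log2 signals per probe set, deposited by the authors and made with RMA per the submitters' processing notes. The version of RMA, its background step and its normalization settings were not given in the sources used here. The deposited medians lay between 6.89 and 6.92, as between-array normalization leaves them. RMA compresses the changes of dim probe sets, and the tables hold no detection call, so no probe set could be called absent. A second table held log2 PLIER signals with an offset of 16, per the file headers. Its column names show the group of each array but not its replicate number. They also carry 2 array codes, the first on 4 arrays and the second on 2, each with equal numbers of both groups. The correlation of the log2 changes of the 2 deposited tables was 0.787 over probe sets, and 0.857 over those above the dim filter. The number of arrays limits the precision.

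The value table holds 14010 probe sets, of which 44 array controls were left out and 13966 were tested. The platform annotation gave 12442 of these 1 gene symbol, 327 several and 1197 none. Symbols were updated through the RefSeq table of the assembly Release 6 plus ISO1 MT, where 12393 probe sets matched by Entrez ID and 4 by symbol, and 46 kept the platform symbol. That table gave the chromosome arm, and no coordinates are printed because the arrays name no build. No gene was named from a probe set with several symbols. For results per gene, the probe set with the highest mean signal over the 6 arrays stood for the gene, which left 10843 genes, 1763 on X and 8982 on the arms 2L, 2R, 3L and 3R. No gene of the Y chromosome was measured.

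Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and calls at an adjusted p under 0.05. The X shift is the median fitted log2 change of X genes minus that of autosomal genes. It was also computed per array from values centred on each gene's mean, with an exact permutation test over the arrays. Gene lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the 28 lists with at least 4 measured genes. The histone list, with 3 measured genes, and the Y chromosome list, with 0, were not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The groups, the tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The rule named the genes of the male dosage compensation complex and a few markers whatever their values, the called genes with the largest changes, and, where fewer than 10 probe sets were called in a direction, the 5 genes of that direction with the smallest p. The markers roX1, roX2, Lsp1alpha and w had no probe set with 1 symbol and were not analysed here.

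The titles give both groups the replicate numbers 1 to 3. Deviations from the group means correlated between same-numbered arrays at 0.17, 0.28 and 0.52 over probe sets, so the numbers were taken to pair the samples, and a fit with the number as a block was an alternative. This pairing comes from the numbers in the titles and from these correlations, and the labels do not say what the numbers share.

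The script was tested on simulated data with the real probe sets and 100 changes of each size. It called 42% of changes of 0.5 and 91% of changes of 1 on the log2 scale, and 2 of 11719 unchanged probe sets. A simulated X shift of -0.1, larger than the -0.038 of the real data, came back as -0.10. The simulated noise was independent between probe sets and between arrays, whereas same-numbered real arrays deviated together. These shares therefore check the script and need not hold for the real arrays. Alternatives were the PLIER table, quantile normalization, centring on the autosomal median, a filter that left out the dimmest 40% of probe sets, the replicate block, another variance model, array weights, means over the probe sets of a gene, stricter thresholds, and leaving out each array. Leaving out replicate 2 of both groups and the fits by array code were added after the data were seen.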

Results

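Gene expression was profiled in 3 arrays of wild type larvae and 3 arrays of mle/mle larvae, all labelled as the last larval instar. The gene mle encodes an RNA helicase of the MSL complex, which raises transcription of the single male X chromosome. The title of the series names aneuploid effects and a shift between X and autosomes, so the comparison asks how expression of X and autosomal genes differs without normal mle. Each array gave 13966 tested log2 signals, and the correlation between any 2 arrays lay between 0.987 and 0.997. The median SD of a probe set between replicates was 0.11.

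The probe set of mle read 5.45 ± 0.10 (SD, n = 3) in wild type and 5.34 ± 0.08 (SD, n = 3) in mle/mle, a log2 difference of -0.10 that did not pass the test (SE 0.08, adjusted p = 0.9997 by limma). The labels do not give the allele, and a mutation that leaves the transcript in place would not be seen here, so this value does not check the genotype. The other measured members of the complex, msl-1, msl-2, msl-3 and mof, differed by -0.05, -0.05, -0.03 and 0.01 on the log2 scale. The kinase gene JIL-1, whose product is enriched on the male X, differed by 0.06. None of these 6 genes passed the test. Of their probe sets only that of msl-2 was bright enough for the dim filter. Those of mle, msl-3, mof and JIL-1 lay below the lower quartile of signals on every array (5.80 to 5.84). RMA compresses changes of such probe sets, so small differences there do not exclude larger ones. In the PLIER table the direction turned for msl-1 (0.12), msl-2 (0.12), mof (-0.05) and JIL-1 (-0.02), none past the test, and mle differed by -0.27 (adjusted p = 1.0). The RNAs roX1 and roX2, which guide the complex, were not analysed here.

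In mle/mle larvae 3 probe sets were higher and 5 lower than in wild type. Amy-d, an alpha-amylase of the gut, rose by 1.30 on the log2 scale (SE 0.10, adjusted p = 0.0076), from 8.74 ± 0.17 to 10.04 ± 0.09 (SD, n = 3 each), which is 2.47 times the wild type signal. Its neighbour Amy-p is nearly identical in sequence and may share this probe set's signal. CG10911 rose by 1.13 (SE 0.13, adjusted p = 0.049), and a probe set annotated to 2 genes rose by 0.85. The CG10911 call lay at the threshold and was lost in most settings that keep every array. By limma the adjusted p was 0.14 in the PLIER table, 0.074 after quantile normalization and 0.064 after centring. With the dim filter it was 0.058, with the other variance model 0.052, and with means over probe sets 0.0505. CG13461 fell by 1.02 (SE 0.08, adjusted p = 0.0076), from 10.35 ± 0.04 to 9.33 ± 0.10. The cytochrome P450 gene Cyp6a9 fell by 0.90, CG17362 by 0.86, CG17105 by 0.77 and Listericin, an antibacterial peptide gene, by 0.78, with adjusted p between 0.021 and 0.043. CG17105 fell by 1.74 in the PLIER table (adjusted p = 0.035). In all 8 probe sets the values of the groups did not overlap, which such calls with 3 arrays per group nearly ensure. Among the rises with the smallest p that did not pass were CG10912 (0.53, adjusted p = 0.067), the phosphatase gene Alp7 (0.68, adjusted p = 0.091) and the polarity kinase gene par-1 (0.54, adjusted p = 0.095). The other 2 probe sets of par-1 differed by 0.08 and -0.04.

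At an unadjusted p under 0.05 there were 604 probe sets, 416 higher and 188 lower. This balance was 991 higher and 889 lower without replicate 2 of both groups, and 188 higher and 211 lower within the array code of 4 arrays of the PLIER table. With the replicate number as a block there were 1003, 634 higher and 369 lower. Chance alone would give 698 if probe sets were independent, so the 604 lie below that number and the 1003 above it. Probe sets are not independent, so 698 is a rough guide. In the other splits of the 6 arrays, 0.29% to 14.6% of chromosome 3 genes had such a p. That range also holds shared differences between arrays and between groups, so it does not measure the dependence of probe sets. Groups did not overlap in 8.36% of all probe sets. The share is 10% by chance where all 6 arrays are exchangeable, which same-numbered arrays that deviate together are not, and it was 3.3% to 13.2% in the 3 other splits that part every pair. In the same blocked fit, Amy-d, CG13461, CG17362 and Listericin stayed called, whereas Cyp6a9 and CG17105 (both adjusted p = 0.058), CG10911 (adjusted p = 0.075) and the probe set of 2 genes (adjusted p = 0.0501) did not. The block also called CG4783 (0.81, adjusted p = 0.037) and Eig71Ed (-0.90, adjusted p = 0.021), named here after their values were seen. The count was 0 without wild type replicate 1, wild type replicate 3, mle/mle replicate 1 or mle/mle replicate 3, and 145 without mle/mle replicate 2. The changes kept their size when 1 array was left out, from 1.21 to 1.38 for Amy-d, -1.07 to -0.97 for CG13461 and -0.95 to -0.84 for Cyp6a9. Without replicate 2 of both groups, a pair of arrays that stood apart, 453 probe sets were called, 313 higher and 140 lower, with all 8 among them. The PLIER table gave 4 calls, all among the 8, and 1 with the array code as a block.

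**Figure D1:**
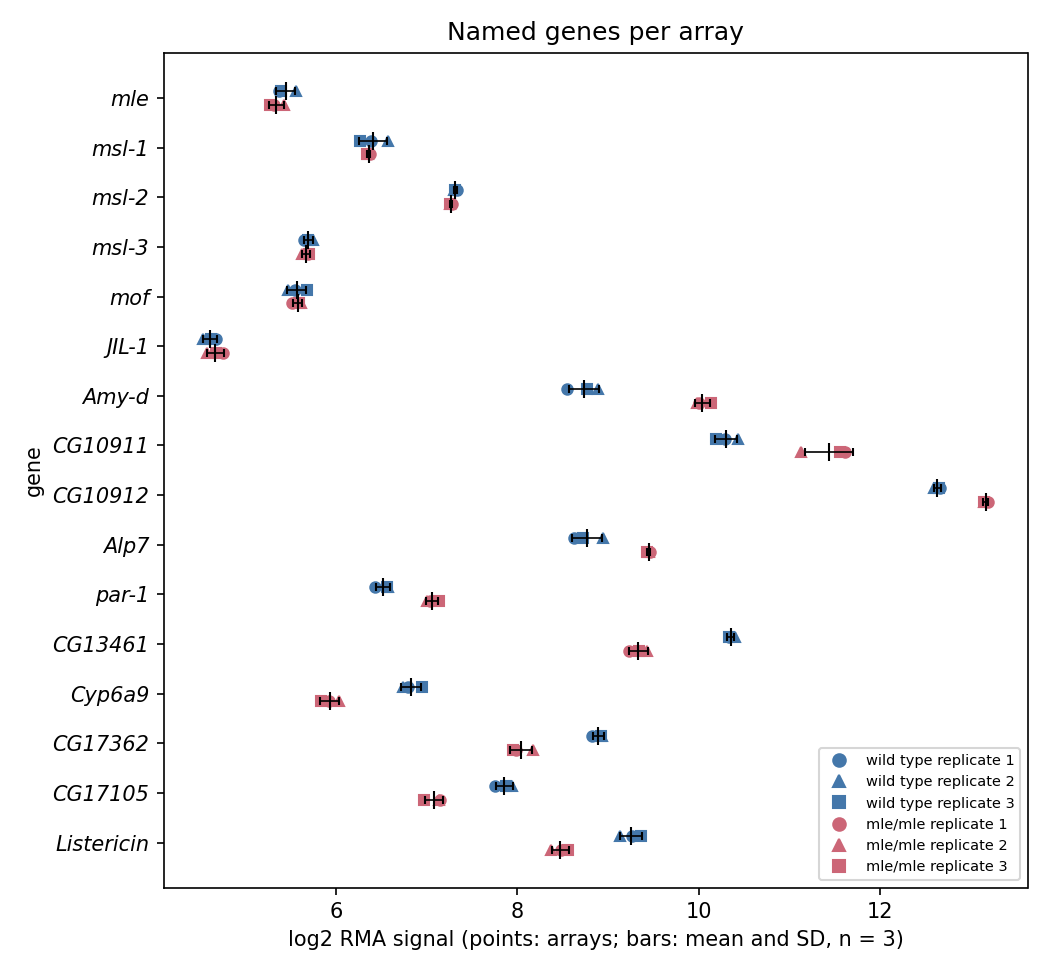
Log2 RMA signal (x axis) of the named genes (y axis) on each array, with wild type in blue and mle/mle in red, and bars for the mean and SD of 3 arrays. The groups are apart for Amy-d (8.74 against 10.04) and CG13461 (10.35 against 9.33) and overlap for mle (5.45 against 5.34).

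Genes on X were slightly lower in mle/mle relative to autosomal genes. The median log2 change was -0.02 over 1763 X genes and 0.01 over 8982 autosomal genes, a shift of -0.038, or 0.974 times. A negative change was seen in 62.2% of X genes, against 41.6% to 45.6% of the genes of each large autosome arm and 47.4% of the 57 genes of chromosome 4. Per array, the X minus autosome value was 0.020 ± 0.021 in wild type and -0.019 ± 0.031 in mle/mle (SD, n = 3 each). The groups overlapped and the exact two-sided permutation p was 0.30, where 3 against 3 arrays cannot go below 0.10. It was lower in mle/mle in all 3 same-numbered pairs, by -0.040, -0.027 and -0.051 (exact sign-flip p = 0.25, the smallest that 3 pairs allow). Camera with the preset correlation gave p = 3.3e-05 for X genes, while the p was 0.19 with an estimated correlation. That last result hung on 1 array, since without mle/mle replicate 2 camera gave p = 0.037 with an estimated correlation. The fry test of limma, which sets X genes against no change and not against autosomal genes, did not pass, nor did it after each array was centred on its autosomal median. Testis and ovary genes, read here because the sex of the wild type larvae is not given, had array medians of 0.035 ± 0.160 and 0.001 ± 0.039 in wild type and 0.009 ± 0.208 and -0.006 ± 0.046 in mle/mle (SD, n = 3 each), on the same centred scale. Within the array codes of the PLIER table the shift was -0.056 over 4 arrays and -0.072 over 2, and with the code as a block it was -0.064.

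**Figure D2:**
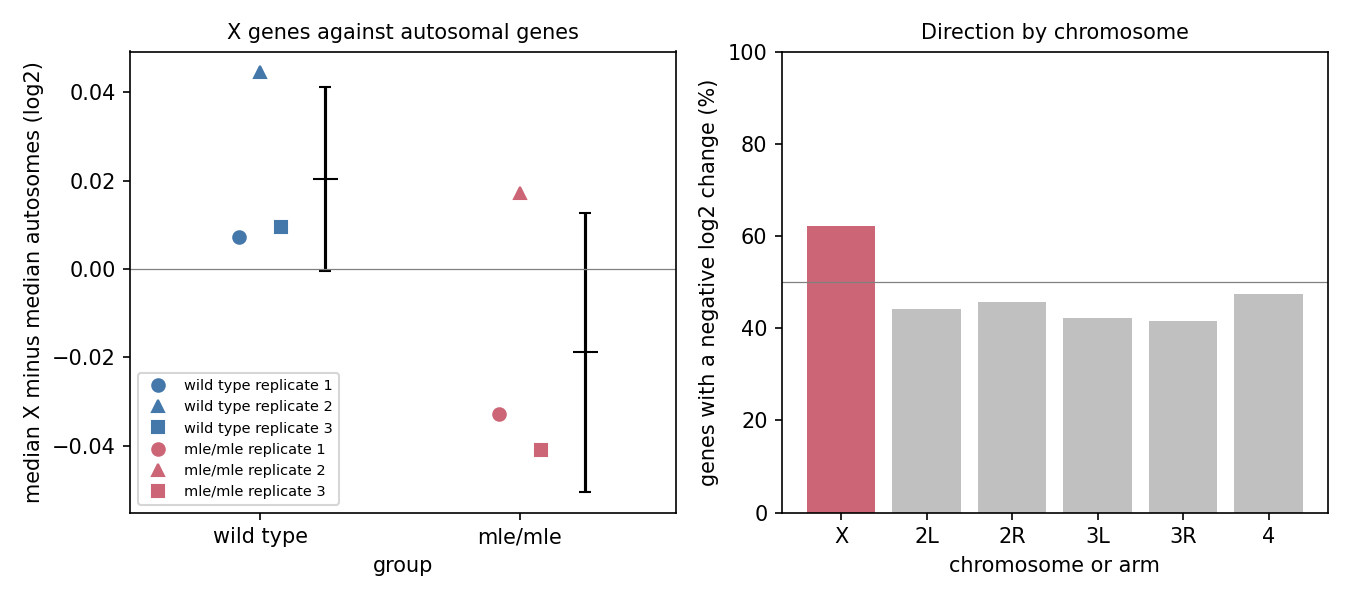
Left, the median log2 signal of X genes minus that of autosomal genes on each array (y axis) by group (x axis), with the mean and SD of 3 arrays beside the points. Right, the percentage of genes with a negative log2 change (y axis) by chromosome or arm (x axis), which is 62.2% on X.

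By chromosome, the 7 called probe sets with 1 gene lay on 2R (2 higher, 2 lower), 3L (2 lower) and 2L (1 lower), and none on X. Limma thus called 0 of the X genes, where 46 had an unadjusted p under 0.05. Those were 15 higher and 31 lower on X, against 327 higher and 129 lower on the autosome arms (Fisher's exact test of direction, two-sided, p = 2.3e-07, over genes, which are not independent replicates). This direction test did not pass without mle/mle replicate 1 (11 higher and 13 lower on X, Fisher's exact p = 0.077). Nor did it within the array code of 4 arrays of the PLIER table (13 and 22, Fisher's exact p = 0.11). It passed in all other settings. Without replicate 2 of both groups, 47 X genes were higher and 194 lower at an unadjusted p under 0.05, against 770 and 544 autosomal genes (Fisher's exact p = 3.8e-30). Past adjustment there, 10 X genes were higher and 22 lower, against 255 and 95 autosomal genes (Fisher's exact p = 3.8e-06). Past adjustment without mle/mle replicate 2 alone, 3 X genes were higher and 1 lower, against 98 and 21 autosomal genes (Fisher's exact p = 0.55). The share of genes at an unadjusted p under 0.05 was 2.61% on X, 5.51% on 2L, 6.89% on 2R, 3.99% on 3L and 4.15% on 3R. The lower share on X (Fisher's exact p = 2.4e-06 against the autosome arms, over genes) was not seen without replicate 2 of both groups, where it was 13.7% on X against 14.6% on the autosome arms (Fisher's exact p = 0.32).

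Of 28 gene lists, camera with the preset correlation called 9, of which 5 were higher and 4 lower in mle/mle. None was called with an estimated correlation (smallest adjusted p = 0.27) or by fry for a shared direction (smallest adjusted p = 0.16). The salivary gland glue and secretion list is mostly of proteins secreted at the end of larval life. It also holds the Eig71E genes, which are used below as a measure of larval age. It had a median change of -0.23 with 19 of 21 members negative (adjusted p = 7.2e-11, and adjusted p = 0.52 with an estimated correlation). No member passed over all probe sets. Adjusted over the list alone, 4 were lower: Sgs5bis (-1.28), Pig1 (-0.55), Sgs8 (-0.49) and Eig71Ee (-0.47). With the replicate block 8 were lower over the list alone, and 1, Eig71Ed, over all probe sets. Without replicate 2 of both groups the median was -0.41 and 11 of the 21 were lower over all probe sets. In the PLIER table the median was -0.40.

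The gut digestive enzymes had a median change of 0.10 with 38 of 51 members positive (adjusted p = 2.7e-05, and adjusted p = 0.79 with an estimated correlation). Amy-d was called over all probe sets. Adjusted over the list alone, 7 were higher and 3 lower. The higher ones included the maltases Mal-A6 (0.56) and Mal-A1 (0.48) and the protease Jon44E (0.81), and the lower ones were the proteases betaTry (-0.58), Jon99Fi (-0.61) and Jon25Bi (-0.40). Detoxification genes had a median of 0.06 with 74 of 104 positive (adjusted p = 0.00076, and adjusted p = 0.79 with an estimated correlation). Their only called member over all probe sets, Cyp6a9, went the other way. Adjusted over the list alone, Cyp28d1 (0.71), Ugt49B1 (0.50) and Cyp28d2 (0.49) were higher and Cyp6a9 lower. Over this list alone 3 were higher and 1 lower with the replicate block, but 0 and 1 in the PLIER table. Hemocyte and crystal cell genes had a median of 0.17 with 20 of 25 positive (adjusted p = 0.00023, and adjusted p = 0.27 with an estimated correlation), with no called member. The hemolectin gene Hml, a hemocyte marker, differed by 0.58 (adjusted p = 0.96). Without replicate 2 of both groups the calls over all probe sets were 16 higher and 2 lower for digestive enzymes, 18 and 2 for detoxification, and 4 and 0 for hemocytes. The median was 0.16 without mle/mle replicate 2 for digestive enzymes, 0.036 without wild type replicate 1 for detoxification, and 0.11 without wild type replicate 3 or mle/mle replicate 1 for hemocytes, all still called. Without replicate 2 of both groups the medians were 0.17, 0.10 and 0.18, and they were 0.08, 0.11 and 0.10 in the PLIER table. Within the array code of 4 arrays these 3 lists were not called (adjusted p = 0.10, 0.17 and 0.065), while their medians were 0.11, 0.08 and 0.12 with 2 arrays in each group.

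The other called lists had no called member. Their medians were -0.08 for cell cycle and DNA replication (33 of 38 negative, adjusted p = 1.5e-05), 0.07 for mitochondrial ribosomal proteins (52 of 64 positive, adjusted p = 0.00076), 0.15 for glycolysis and the pentose phosphate pathway (14 of 18 positive, adjusted p = 0.044), -0.07 for testis (32 of 42 negative, adjusted p = 0.044) and -0.05 for the proteasome (27 of 28 negative, adjusted p = 0.030). With an estimated correlation the adjusted p was 0.79 for both cell cycle and mitochondrial ribosomal proteins and 0.91 for the other three. With the replicate block the proteasome list was no longer called (adjusted p = 0.080), nor was it in the PLIER table (adjusted p = 0.15). Some settings that keep every array also ended calls: quantile normalization (adjusted p = 0.057), centring (0.073), the dim filter (0.089) and array weights (0.36) for testis, and quantile normalization (0.084) and the dim filter (0.081) for glycolysis. The median of cell cycle genes was -0.12 in the PLIER table and without replicate 2 of both groups, and that of testis genes -0.11 in the PLIER table. Without replicate 2 of both groups it was 0.28 for glycolysis and -0.22 for the proteasome, which lay at -0.09 after quantile normalization. Single arrays decided 4 of these calls. The glycolysis call was lost without wild type replicate 1 (median 0.12), wild type replicate 2 (0.11), mle/mle replicate 1 (0.10) or mle/mle replicate 3 (0.07), and its median was 0.33 without mle/mle replicate 2. The proteasome call was lost without wild type replicate 1 (-0.02), wild type replicate 3 (-0.001), mle/mle replicate 1 (-0.02) or mle/mle replicate 3 (-0.02), and its median was -0.14 without wild type replicate 2 and -0.13 without mle/mle replicate 2. The call of mitochondrial ribosomal proteins was lost without wild type replicate 2 (0.02), mle/mle replicate 2 (0.06) or both (0.02). The testis call was lost without wild type replicate 1 (-0.03), wild type replicate 3 (0.002), mle/mle replicate 2 (0.10) or replicate 2 of both groups (-0.02), while its median was -0.13 without wild type replicate 2 or mle/mle replicate 1 and -0.12 without mle/mle replicate 3. The adjusted p of the 19 other lists lay between 0.080 and 0.94. Among these, innate immunity passed the mixed test of fry, which asks for change whatever its direction (adjusted p = 0.0016). This list also passed that test with the replicate block (adjusted p = 0.019) and in the PLIER table with the array code as a block (adjusted p = 0.0070). In the PLIER table without that block it did not (adjusted p = 0.20). Listericin, not called in the PLIER table (adjusted p = 0.28 by limma), was its called member. PGRP-SC2 (-0.41) was lower too when adjusted over the list alone. With the replicate block, 3 members of this list were higher and 2 lower over the list alone. The mixed test also passed for digestive enzymes (adjusted p = 0.0085) and detoxification (adjusted p = 0.040), but with the replicate block it did not (adjusted p = 0.10 and 0.20), and there it passed for glue and secretion (adjusted p = 0.023, against 0.053 without the block).

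**Figure D3:**
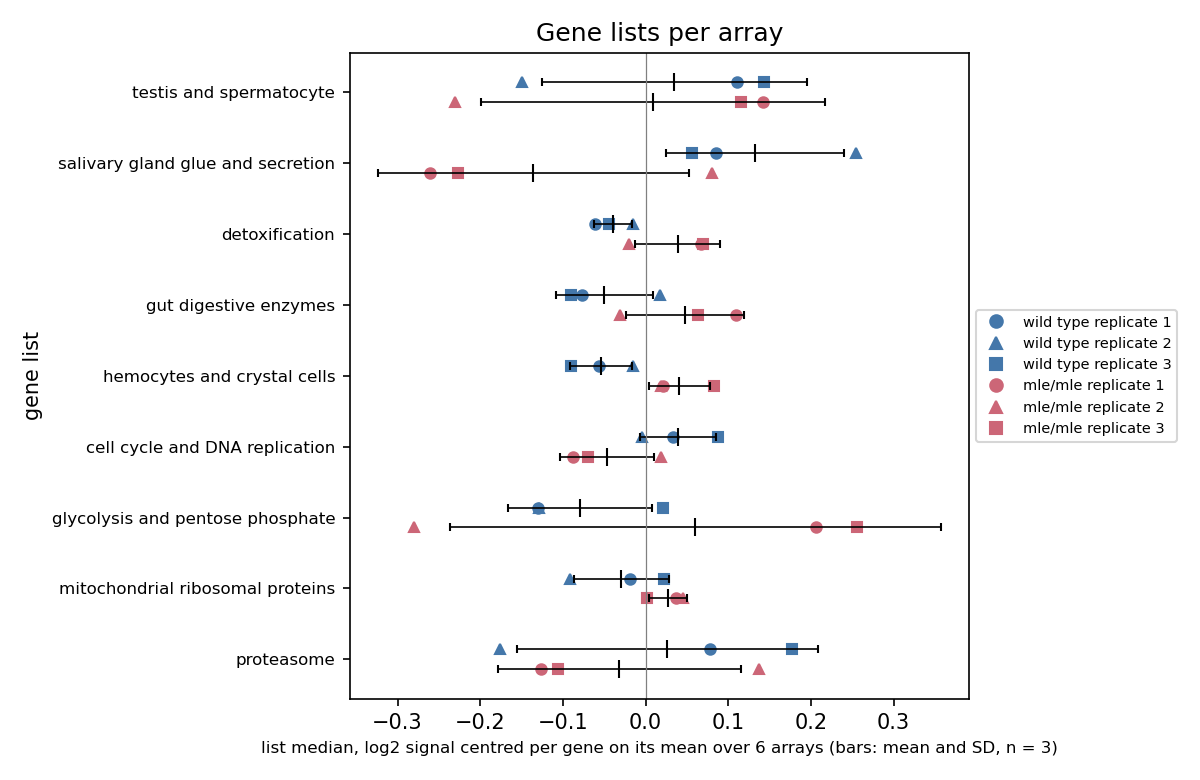
Median over the genes of each called list (y axis) of log2 signals centred on each gene's mean over the 6 arrays (x axis), per array, with bars for the mean and SD of 3 arrays. The groups are apart for hemocytes (-0.05 against 0.04), while mle/mle replicate 2 lies beyond a wild type array for glue and secretion (0.08 against 0.06).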

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

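The fits without replicate 2 and by array code were chosen after the data were seen. The X shift kept its direction under all 19 alternatives, from -0.064 with the PLIER table to -0.026 without wild type replicate 2. Some of these could not move it: the replicate block, the other variance model and centring returned -0.038. The array code as a block likewise returned the -0.064 of the PLIER table. The camera call held at the preset correlation, with p from 6.3e-07 to 0.014. With an estimated correlation camera passed only without mle/mle replicate 2 (p = 0.037). The count of 8 probe sets moved to 4 with the PLIER table, 2 at an adjusted p under 0.01, 3 with a log2 change of at least 1, 1560 with array weights, 453 without replicate 2 of both groups, 1 for the PLIER table with the array code as a block and 0 within the array code of 4 arrays, where limma had 399 at an unadjusted p under 0.05. Array weights ran from 0.284 to 7.10 and their estimation stopped before it converged, so that count carries little weight. Leaving out 1 array gave 0 to 145 calls. The calls by chromosome, 7 genes, became 4, 2, 1267, 382, 1 and 0 in the same settings (none of them sets a log2 minimum) and 0 to 123 without 1 array. The 9 called lists became 3 within the array code of 4 arrays, 0 with an estimated correlation and 0 by fry. The testis list was called at -0.134 without wild type replicate 2, and turned, uncalled, to 0.002 without wild type replicate 3 and 0.10 without mle/mle replicate 2. The proteasome list turned to 0.036 within the array code of 4 arrays, also uncalled. Smaller groups lower the power of these fits, and for the other changes the cause was not tested. The replicate block gave 6 calls, of which 4 were among the 8, and 8 lists, a shift of -0.038, and changed no other call than those given with the results. Another pseudocount was not run, since the values were deposited on the log2 scale. Signal over background could not be read from these tables.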

Other observations

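The tests of wild type females, larval stage, larval age, older larvae in replicate 2 and strain were chosen only after values bearing on them had been seen, as was the comparison of list medians between arrays. For close linkage and gut tissue, whose bounds were set before, the error of the value was added after it was seen, and without that error both values fell on the side that argues against the explanation. Other answers also hung on the rule. For larval age, a first rule that left out the error of the group difference came out in favour, and the interval below replaced it after its value was seen. For wild type females, another rule tried after the values were seen, a bound on the rise of testis genes, came out against, and was dropped for the rule first written. For strain, a first reading of the pooled chromosome 2 share came out in favour and was dropped, since that share holds the genes that prompted it.

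Of the 28 lists, 3 had array medians that did not overlap between the groups (10.7%). These were hemocytes and crystal cells, eye pigment and pigment transport (-0.039 ± 0.022 in wild type, 0.015 ± 0.036 in mle/mle) and growth and nutrient signalling (-0.026 ± 0.028 and 0.028 ± 0.025, SD, n = 3 each). The last 2 were not called by camera. Within the same-numbered pairs, 7 lists (25%) had one direction in all 3, these 3 with fat body, oxidative phosphorylation and odorant receptors higher in mle/mle, and glue and secretion lower. If each pair falls either way alike, 25% would do so by chance.

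Genes on X were lower relative to autosomal genes in mle/mle. Dim probe sets are argued against, because the shift over brighter probe sets was -0.047, from -0.066 to -0.031 without 1 array. The size of the shift varied with signal. In 4 classes of genes from dimmest to brightest it was -0.024, -0.029, -0.043 and -0.063, so the -0.038 over all genes is not 1 common size. That the shift rests on the replicate 2 arrays is argued against too: without them it was -0.038, and -0.047 to -0.039 in the 4 remaining pairs of arrays. The X minus autosome value was itself higher in replicate 2 than in the other arrays, by 0.036 in wild type and 0.054 in mle/mle. Differences of about the size of the group difference (-0.039) thus also arose within each group. A strain difference between the groups, on X or on the autosomes, was not tested for this shift and cannot be told apart from mle. Females among the wild type larvae stay open: testis genes were higher in mle/mle in 1 of 3 pairs, with median differences from -0.23 to 0.0005. A difference in larval age also stays open, as does mle itself: the group difference at equal level of the Eig71E genes, late ecdysone targets, was -0.014 with a 95% interval from -0.053 to 0.025, which holds both 0 and the unadjusted -0.039. That fit leaves out the pairing, and within pairs the X value fell by 0.040, 0.027 and 0.051 where Eig71E fell by 1.25, 0.88 and 0.48, so the largest X drop had the smallest Eig71E gap, but the paired interval, -0.36 to 0.26 around -0.052 with 1 residual degree of freedom, is too wide to tell age and genotype apart.

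The X minus autosome value of the 6 arrays was set against the median of each of the 28 lists and of the Eig71E genes, which were picked after the arrays had been looked at. None of the 29 relations passed adjustment. The glue and secretion list holds the Eig71E genes, so those relations are not separate. The permutations moved all 6 arrays freely and ignored group and pairing, although same-numbered arrays deviate together. Glue and secretion, Eig71E and the X value were each lower in mle/mle in all 3 pairs, so their r also holds the group difference. Pearson's r was 0.98 for glue and secretion (exact permutation p = 0.014, adjusted p = 0.16), 0.94 for Eig71E (exact permutation p = 0.0028, adjusted p = 0.081), -0.92 for oxidative phosphorylation (exact permutation p = 0.022, adjusted p = 0.16), -0.89 for the fat body (exact permutation p = 0.017, adjusted p = 0.16) and -0.84 for glycolysis (exact permutation p = 0.036, adjusted p = 0.21). Spearman's rho was 0.77, 0.94, -0.89, -0.83 and -0.71, with exact permutation p of 0.10, 0.017, 0.033, 0.058 and 0.14 and adjusted p of 0.43 for the first 4 and 0.44 for glycolysis. Without the 2 arrays farthest from the list's median, r was 0.96, 0.90, -0.84, -0.60 and -0.18, so the glycolysis relation rests on those arrays.

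With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. As large a shift was found in 3 of the 10 splits, the real one included (0.038, highest other 0.048). As many called probe sets were found in 1 split (8, highest other 0). As many called lists were found in 5 splits (9, highest other 12). Among the 4 splits that part all 3 pairs, the others reached 0 probe sets, a shift of 0.023 and 10 lists.

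Replicate 2 stood apart from the other arrays in both groups. Damaged RNA was not settled by its test: 0 of 3 control transcripts had a 3' minus 5' difference beyond the other 4 arrays on one side in both replicate 2 arrays. Any 2 arrays would usually miss that bound, so missing it decides little. In wild type replicate 2 the GAPDH difference (1.72) was the highest of all arrays. In mle/mle replicate 2 the differences of actin (1.31), GAPDH (1.46) and eIF-4a (1.85) lay within the range of the other 4 arrays. Older larvae stay open: Eig71E genes were higher in replicate 2 by a median of 0.88 in wild type and 0.46 in mle/mle, as the median of changes per gene, below the 1 set for that explanation, but by 1.40 and 1.38 as the change of array medians, above it. The early glue genes (Sgs), which that explanation needs lower in both groups, differed by -0.12 and 0.29 per gene and by -0.31 and 0.32 as array medians. No biological explanation was tested beyond these.

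The 8 genes with the smallest p among the rises, a number set by where the run ended, all lay on arm 2R, which holds 20.1% of the measured genes and mle itself, while 2R held 1 of the next 12 rises and 6 of the first 20 falls. A second chromosome of another strain, carried along with mle, stays open. Of chromosome 2 genes 6.23% had an unadjusted p under 0.05, which includes the genes that prompted the question. Arm 2L, which holds none of them, had 5.51% against 4.08% on chromosome 3 (Fisher's exact p = 0.012, over genes). Fitted over genes the difference was 1.42 points. The largest other in size among the 10 splits ran the other way (-2.22). The highest other in the same direction was 0.30, in a split that parts every pair. The 10 splits are too few for a share under 0.05. Close linkage to mle was not settled by its test, with 4.38% of the 137 nearest measured genes against 7.06% of the rest of 2R (Fisher's exact p = 0.30), although 0 of the 8 genes lay among those neighbours. More gut tissue was not settled either: digestive enzyme genes outside 2R had a median change of 0.052 (bootstrap interval over genes 0.005 to 0.124) against 0.21 on 2R. The 2R value includes Amy-d, Mal-A6 and Jon44E, which are among the 8 genes that prompted the question. It can thus be too high a bar for this explanation. CG10911 and CG10912 are neighbours with 1 reference gene between them.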
